A study of Mus musculus with 12 samples.

How the data were processed

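Messenger RNA was sequenced from the outer kidney cortex of 12 mice that were 12 weeks old. Tg26 mice, which carry a defective HIV provirus as a transgene and develop HIV-associated nephropathy, and wild-type (WT) mice each received INT-747 or nicotinamide riboside (NR), which gave 4 groups of 3 mice. Doses, length and route of treatment, sex and strain are not given in the sources used here, and no group without treatment was analysed here. Libraries were stranded TruSeq mRNA libraries. The labels name bcl2fastq 2.17, cutadapt 1.18, STAR 2.7.0f and RSEM 1.3.1 as the authors' tools and mm10 as the genome build, without their order or settings. The deposited values are RSEM expected counts (expected_counts) per gene, not scaled to library size. All 55450 gene IDs of the deposited table carry version suffixes, and every ID with its symbol was found in release 21 of the mouse GENCODE annotation, from which chromosome, start and end were taken. The annotation release the authors used and their rule for rounding are not stated; 0 of the deposited values were not whole numbers.

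Total counts per library ran from 22286343 to 28952177. Genes were kept with the filterByExpr function of edgeR on the 4 groups, which left 15708 genes. Counts were scaled by TMM, and expression is given in counts-per-million (CPM) as the mean and SD over 3 mice. All 12 libraries entered one edgeR quasi-likelihood fit with robust estimation and a mean per group, which left 8 residual degrees of freedom. The common biological coefficient of variation was 0.214. Each contrast was tested with the quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called. Log2 fold changes are given with their standard error (SE) from the same fit. The p-values measure the spread between mice of a group. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

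The contrasts were Tg26 minus WT under INT-747, Tg26 minus WT under NR, INT-747 minus NR in WT mice, INT-747 minus NR in Tg26 mice, and the interaction, which is the difference between the genotype effects. Choices of test, filter, gene lists and rule for naming genes were made before the data were examined, and later additions are named as such. Among called genes with a mean log2 CPM of at least 1 and no overlap between the replicates of both groups, the 12 with the largest change in each direction were named, leaving out predicted genes, clones and pseudogenes. Where fewer than 10 genes qualified, those of smallest p were added up to 10, as genes not past the threshold. For each list up to 4 members of smallest p could be named, and the tested members of the lists for FXR targets, NAD metabolism, tubular injury and podocytes. Some genes to which these rules apply are not reported here. Genes singled out in addition are described as chosen after their values were seen.

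The 36 lists covered nephron segments, other kidney and immune cell types, possible admixed tissues, injury and fibrosis, metabolism, FXR targets, NAD metabolism and stress responses. They were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 34 lists with at least 3 tested members. Genes called when p was adjusted over the members of a list alone are given as adjusted over the list alone. Camera with an estimated correlation and fry, which asks whether the members of a list move one way on balance, were run as alternatives. At the estimated correlation 0 lists were called in any of the 5 contrasts.

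Also run were RLE size factors, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2, limma-voom, edgeR without robust estimation, a fit of only the 2 groups compared, a replicate block, a term for the sex of the mouse as read from Xist and Y-linked genes, removal of genes on the Y chromosome and Xist, and leaving out each library. Chosen after seeing the data were a clock score as a covariate, with and without the sex term, DESeq2 with the sex term, camera with an estimated correlation and fry with either term, and the naming rule applied to the fit with the sex term. The clock score is the mean log2 CPM of 10 clock output and repressor genes, such as Dbp, Per2 and Nr1d1, minus that of 4 genes of the opposite phase, such as Arntl and Npas2. The fit was tested on simulated data in which 100 of 15708 genes were changed 2-fold and 100 others 4-fold. It recovered 72% and 96% of them in the INT-747 genotype contrast with 4 unchanged genes called, 74% and 93% in the Tg26 treatment contrast with 11, and 42% and 83% in the interaction with 10. Replicate numbers are not stated to pair mice, so no pairing was used.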

Results

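Kidney cortex transcriptomes of Tg26 and WT mice were compared under INT-747, also known as obeticholic acid, an agonist of the bile acid receptor FXR, and under nicotinamide riboside, a precursor of NAD. Each of the 4 groups held 3 mice. Total counts per library were 22286343 to 27255336 in WT mice under INT-747, 23957530 to 24752120 in Tg26 mice under INT-747, 23035649 to 26300729 in WT mice under NR and 23790167 to 28952177 in Tg26 mice under NR. Transcripts encoded in mitochondria took 7.94% to 9.97% of the counts, and the most abundant gene, mt-Co1, took 3.01% to 4.24%. The first principal component held 32.8% of the variance of the 2000 most variable genes and the second 23.1%. Without untreated mice, a treatment difference here is that between INT-747 and NR.

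The sex of the mice was read from Xist, which is transcribed from the inactive X chromosome, and from 4 genes on the Y chromosome. Xist had 5816 counts in Tg26 replicate 3 under NR and 1 to 8 counts in the other 11 libraries. Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in that library and 1038 to 1630, 1279 to 2230, 339 to 716 and 375 to 687 counts in the others. The library thus had the pattern of a female mouse and the other 11 that of male mice. With a sex term, which leaves the Tg26 mean under NR to the remaining 2 libraries, the common biological coefficient of variation was 0.171.

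Libraries also differed in genes of the circadian clock. The clock score was 2.75 ± 0.376 (SD, n = 3) in Tg26 mice and 0.194 ± 0.434 in WT mice under INT-747, without overlap, a difference of 2.55 with a standard error of 0.331. Under NR it was 2.34 ± 1.56 in Tg26 mice and 0.933 ± 2.04 in WT mice, and both groups were spread widely: 2.87, 3.57 and 0.576 in Tg26 replicates 1, 2 and 3, against 3.25, 0.156 and −0.608 in WT replicates 1, 2 and 3. In a fit with the score as a covariate, chosen after seeing the data, 238 genes followed it within groups, 97 upward and 141 downward. The genes of the score itself were among those tested. The low score of 0.576 was that of the female library, and this fit had no sex term. The times of collection are not given in the sources used here. Under INT-747 high and low scores each held mice of 1 genotype only, so no value within a score level could be had.

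**Figure D1:**
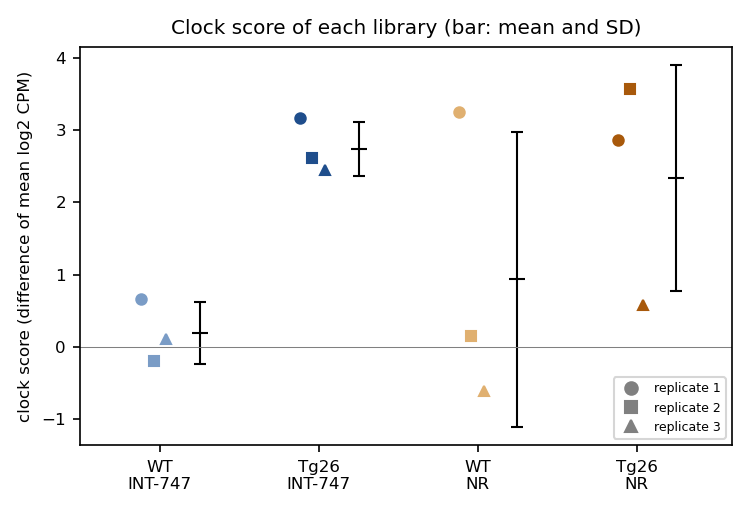
Clock score of each library, the mean log2 CPM of 10 clock output and repressor genes minus that of 4 genes of the opposite phase, by group, with points for replicates and a bar for mean and SD (n = 3). Scores under INT-747 were 2.45 to 3.17 in Tg26 mice and −0.192 to 0.663 in WT mice, while under NR those of both genotypes overlapped.

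The comparison of Tg26 with WT mice under INT-747 asks which transcripts set the diseased kidney apart in mice given INT-747. The chaperone gene Hsph1, which encodes a large heat shock protein (chromosome 5, 149614287 to 149636376, ENSMUSG00000029657.15), was at 175.4 ± 27.3 CPM in Tg26 mice against 72.6 ± 11.4 in WT mice (log2 fold change 1.27, SE 0.21, adjusted p = 0.0415). Its relative Hspa2 (log2 1.21) and Chordc1 (0.83), which encodes a cofactor of Hsp90, rose as well. Nr1i3, which encodes the nuclear receptor CAR, fell from 4.04 ± 0.974 to 0.712 ± 0.0311 CPM (log2 −2.50, SE 0.32, adjusted p = 0.0173), and Cyp26b1, which degrades retinoic acid, fell from 30.5 ± 1.97 to 8.85 ± 1.77 CPM (log2 −1.79, SE 0.20, adjusted p = 0.00891). The noncoding transcript Dio3os (chromosome 12, 110275385 to 110278172) fell from 28.4 ± 8.24 to 5.05 ± 0.621 CPM (log2 −2.49, SE 0.28, adjusted p = 0.00891).

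In all, 42 of 15708 genes were called in this contrast, 18 higher and 24 lower in Tg26 mice, and 10 of them changed at least 2-fold. All 42 separated the 6 mice without overlap, as did 26.0% of all genes, where chance gives 10%. Among the other genes that rose were Sypl2 (log2 0.90), the dynein light chain Dynll1 (0.84), Metrnl (0.79), Them4 (0.77), Mtus1 (0.75), the DNA end resection factor Rbbp8 (0.65), Lamtor5 (0.64) and Ostc (0.61), part of the oligosaccharyltransferase complex. Those that fell were Hpdl (log2 −1.78), Col13a1 (−1.25), Abhd15 (−1.25), Nectin1 (−1.04), Srcin1 (−0.96), the Polycomb gene Cbx7 (−0.92), Tmem140 (−0.82), Gpr146 (−0.78) and Aspg (−0.78).

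Transcripts of fatty acid oxidation and of PPAR-alpha targets were lower as a list in Tg26 mice under INT-747, with 27 of 28 members lower, a median log2 of −0.45 and a camera adjusted p = 6.1e-09. Vnn1, among its members of smallest p, stood at a log2 of −0.95 (SE 0.30), and 0 members were called. The list of the unfolded protein and integrated stress response was higher, with 15 of 20 members higher and a median of 0.46 (adjusted p = 1.33e-05). Adjusted over the list alone, 10 of its members were higher and 1 lower, and the values were 1.08 for Creld2, 0.75 for the disulfide isomerase Pdia4, 0.99 for Sdf2l1 and −1.26 for Sesn2. Macrophage and antigen presentation genes had all 20 members higher (median 0.98, adjusted p = 0.00223), as in Lyz2 (75.3 ± 96.2 CPM against 8.45 ± 2.80) and Fcgr1 (log2 2.71, SE 1.11). Cytokine, chemokine and NF-kB target genes had 17 of 18 members higher (median 0.56, adjusted p = 0.0109), among them Cxcl1 (2.60, SE 1.01) and Ccl2 (3.07, SE 1.33). The macrophage and cytokine values leaned on Tg26 replicate 2 under INT-747. Without it the macrophage median for INT-747 minus NR in Tg26 mice went from −0.82 to −1.68. The cytokine median went from −0.52 to −0.98. Cholesterol synthesis and uptake genes had 18 of 22 higher (median 0.21, adjusted p = 0.0109), with 2 higher and 1 lower adjusted over the list alone. Hmgcs1 stood at 0.67, Dhcr7 at 0.96 and Insig1 at −0.82. Adipocyte genes were lower in 4 of 5 members (median −0.90, adjusted p = 0.0204), 2 adjusted over the list alone, with Lipe at −0.97. Intercalated cell genes were lower in 9 of 10 (−0.24, adjusted p = 0.0477), with Foxi1 at −0.76. Endothelial genes were lower in 14 of 15 (−0.11, adjusted p = 0.0477), with Sox18 at −0.52. For these 8 lists the adjusted p was 0.879 to 0.888 with an estimated correlation.

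The 13 tested FXR targets were not called as a list under INT-747 (7 higher, 6 lower, median 0.16, mean −0.09, adjusted p = 0.974), nor was any of them alone past the threshold over all genes. Slc51a, a bile acid exporter subunit, stood at log2 0.81, the FXR gene Nr1h4 at 0.39 and its target Nr0b2 at −0.59. NAD metabolism genes were not called either (16 IDs higher, 14 lower, median 0.01, adjusted p = 0.762), and Nmrk1, the kinase that phosphorylates nicotinamide riboside, stood at 1.03 (SE 0.25, adjusted p = 0.138). Tubular injury genes had 15 of 16 members higher (median 0.71, adjusted p = 0.0561) and podocyte genes 8 of 15 (0.08, adjusted p = 0.762). Without Tg26 replicate 2 under INT-747 the tubular injury median for INT-747 minus NR in Tg26 mice went from −1.013 to −1.855.

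The number of genes past the threshold in the INT-747 genotype contrast moved with single libraries in edgeR. It was 3, 4 and 10 without WT replicates 1, 2 and 3 and 0, 0 and 6 without Tg26 replicates 1, 2 and 3 under INT-747. It was 77 and 20 without WT replicates 1 and 3 under NR, and 195 without Tg26 replicate 3 under NR. It was 11 with a replicate block, 189 with the sex term, which held all 42, and 2 with the clock score as a covariate, Dio3os (log2 −1.88) and the pseudogene Rpl3-ps1, while Hsph1 stood at 0.88. In the fit without these terms the unadjusted p was under 0.05 for 2403 genes, and DESeq2 called 525 genes and limma-voom 35. The called lists numbered 5 without Tg26 replicate 2 and 14 without Tg26 replicate 3 under INT-747, and 15 without Tg26 replicate 3 under NR.

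Under NR the same genotype comparison asks how the Tg26 kidney differed while an NAD precursor was given. Genes of scarring, tubular injury and immune cells had higher means in Tg26 mice, with a wide spread between the 3 mice. Spp1, which encodes osteopontin, was at 846.5 ± 400.7 CPM against 235.5 ± 25.5 in WT mice (log2 1.85, SE 0.36, adjusted p = 0.125), and Lcn2, a marker of tubular damage, at 30.8 ± 40.8 against 0.952 ± 0.159 (log2 5.02, SE 1.51, adjusted p = 0.144). The gene of smallest p, the interferon-inducible Gbp3 (chromosome 3, 142560026 to 142573209), was at 10.7 ± 3.39 CPM against 1.91 ± 0.211 (log2 2.48, SE 0.37, adjusted p = 0.125). No gene was past the threshold with edgeR, where 3244 had an unadjusted p under 0.05; DESeq2 called 967 and limma-voom 0.

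The other genes of smallest p, none past the threshold at an adjusted p = 0.125, were Npr2 (log2 0.51), a natriuretic peptide receptor, the intermediate filament gene Nes (1.10), Rell1 (0.90), Akr1c18 (0.67), the predicted gene Gm45140 (1.59), Aspg (−0.81), Rbm38 (−1.42), the phenylalanyl-tRNA synthetase gene Farsb (−0.76) and Usp14 (−0.49). Aspg (chromosome 12, 112106679 to 112127559) had 62.3 ± 6.54 CPM in Tg26 and 109.5 ± 8.05 in WT mice under NR, and 63.3 ± 11.3 and 108.5 ± 12.1 under INT-747.

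Of the 34 lists, 14 were called higher and 6 lower in Tg26 mice under NR. All 25 fibrosis and matrix genes were higher (median 1.51, camera adjusted p = 3.1e-16), 24 of them adjusted over the list alone, with values such as 1.05 for Ccn2, 1.04 for Sparc and 0.91 for Tgfb1. Tubular injury genes were higher in 15 of 16 members (median 2.15, adjusted p = 8.2e-11), 13 adjusted over the list alone, as in Timp1 (5.50) and Vim (1.64). Macrophage genes were higher in 20 of 20 (2.05, adjusted p = 3.6e-11), all adjusted over the list alone, as in Tyrobp (2.12) and the class II gene H2-Eb1 (5.27). Cytokine genes (17 of 18, 1.36, adjusted p = 4.5e-07, as in Cxcl2 at 5.44) and T cell genes (13 of 13, 1.77, adjusted p = 3.2e-06, as in Cd4 at 2.62 and Cd5 at 3.26) were higher. So were interferon-stimulated genes (23 of 24, 0.65, adjusted p = 3.2e-06, as in Bst2 at 0.71) and complement genes (13 of 15, 1.02, adjusted p = 6.7e-06, as in Masp1 at 1.54). Neutrophil genes (5 of 5, 2.35, adjusted p = 0.000825, as in S100a9 at 3.23) and B and plasma cell genes (7 of 7, adjusted p = 0.0241) were also higher. The size of these values leaned on Tg26 replicate 1 under NR. Without it the fibrosis median for INT-747 minus NR in Tg26 mice went from −0.77 to −0.03. The macrophage median went from −0.82 to 0.04. Camera at the preset correlation still called 17 lists in the NR genotype contrast without that library.

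Some kidney cell lists were called as well under NR. Podocyte genes were higher in 14 of 15 members (median 0.34, adjusted p = 7.2e-05), as in Cdkn1c (0.87), and loop of Henle genes in 10 of 10 (0.62, adjusted p = 0.000825), as in Cldn16 (1.03) and Umod (0.65). Proximal tubule genes were lower in 16 of 20 (−0.24, adjusted p = 0.00765), as in Slc13a3 (−0.56). Cell cycle genes were higher in 21 of 23 (0.51, adjusted p = 0.00859), as in Mcm4 (0.61), ribosomal protein genes in 28 of 28 (0.15, adjusted p = 0.000882), and immediate early genes in 7 of 11 (0.50, adjusted p = 0.0247). Fatty acid oxidation genes were lower in 26 of 28 members (−0.49, adjusted p = 5.4e-09), 11 adjusted over the list alone, with values such as Decr1 at −0.66, Cpt2 at −0.67 and Acadl at −0.48. Those of the TCA cycle were lower in 16 of 16 (−0.22, adjusted p = 0.000265), as in Dlst (−0.29), and those of the respiratory chain encoded in the nucleus in 36 of 38 (−0.12, adjusted p = 0.000882). Transcripts encoded in mitochondria were lower in 13 of 13 (−0.21, adjusted p = 0.00484), as in mt-Nd2 (−0.46), and NRF2 targets in 14 of 18 (−0.26, adjusted p = 0.000882), as in Nqo1 (−0.61), Gsr (−0.52) and Cat (−0.50). With an estimated correlation the adjusted p of these 20 lists was 0.406 to 0.666. FXR targets (8 of 13 higher, 0.19, adjusted p = 0.497) and NAD metabolism genes (19 of 30 IDs lower, −0.11, mean 0.11, adjusted p = 0.0967) were not called. Pltp stood at 1.87, Abcc3 at 2.09, Pnp at −0.44, the mitochondrial deacetylase Sirt3 at −0.41 and Kynu at 1.90.

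With the sex term, 340 genes passed the threshold in the NR genotype contrast, 285 higher and 55 lower. When the clock score was added to the sex term, 0 genes passed it. The 2 remaining Tg26 libraries had clock scores of 2.87 and 3.57, against 3.25, 0.156 and −0.608 in WT mice. All 4 clock genes of the opposite phase were lower with the sex term (median −1.97), so clock and genotype were not well separated. The naming rule was applied to the fit with the sex term alone after seeing the data. Among genes that rose were the immunoglobulin gene Ighg2b (log2 4.88, SE 0.49), H2-Eb1 (5.84), Lcn2 (5.59), the macrophage gene Cd68 (3.21), the retinoic acid synthase Aldh1a2 (3.19), the chemokine Ccl9 (3.06), Socs3 (2.99) and Plac8 (2.95). Among those that fell were Dio3os (−1.50), the peroxisomal Ehhadh (−1.19), Rbm38 (−1.16), Ndrg1 (−0.99) and Cpt2 (−0.79). The count in the fit without that term was 3 without Tg26 replicate 2 under INT-747, 1 without Tg26 replicate 1, 785 without Tg26 replicate 2 and 333 without Tg26 replicate 3 under NR, and 6 without a filter. With a replicate block it was 0.

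**Figure D2:**
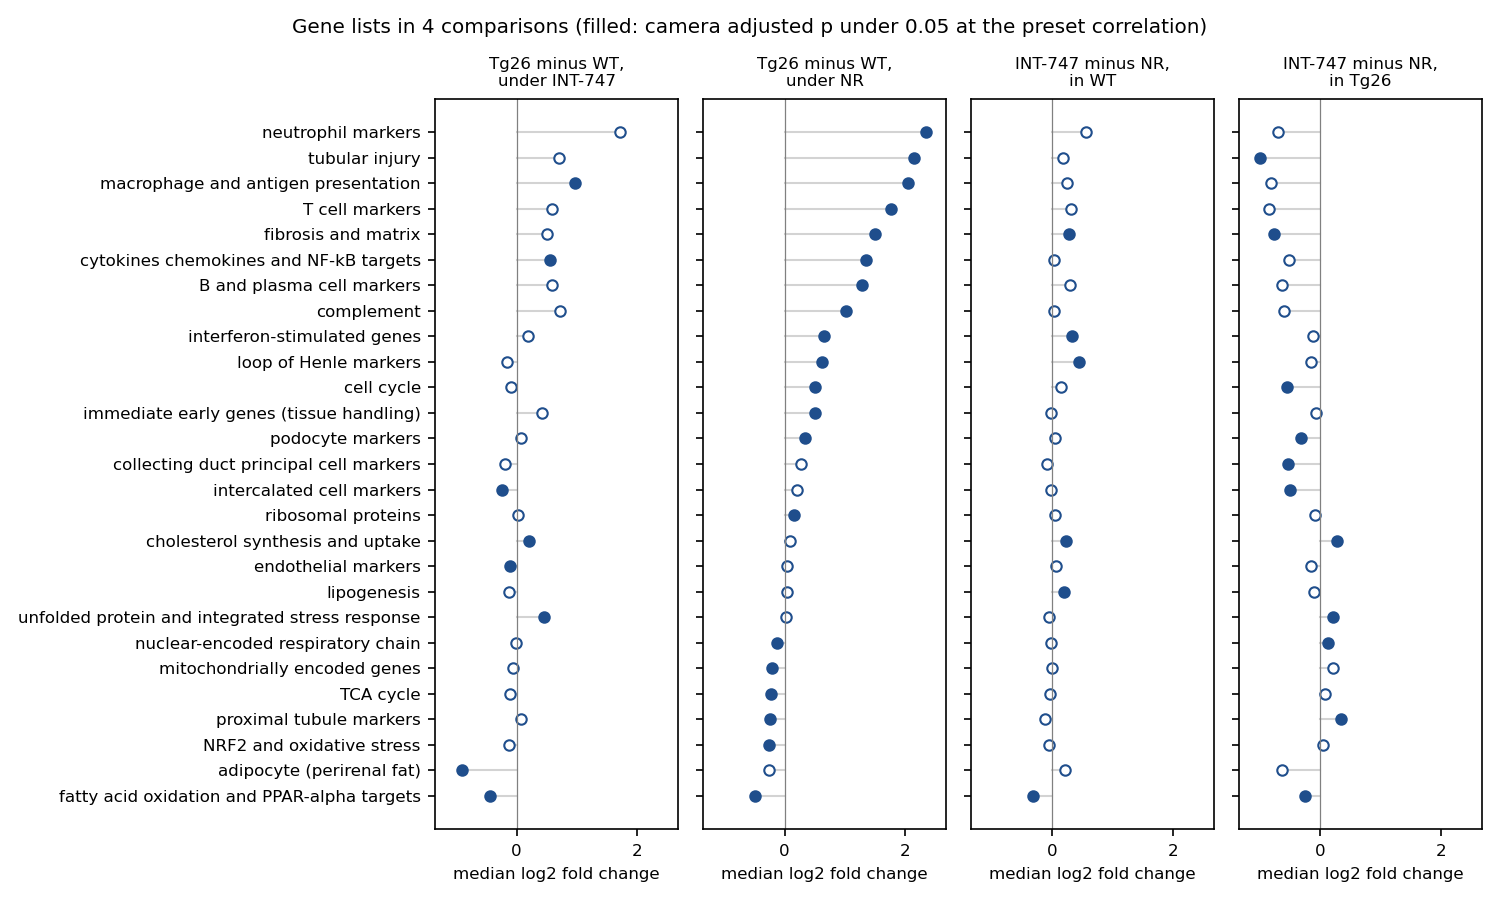
Median log2 fold change of the members of each gene list called in at least 1 of 4 comparisons, with a filled point where camera at the preset correlation gave an adjusted p under 0.05. Fibrosis, macrophage and tubular injury lists had medians of 1.51, 2.05 and 2.15 for Tg26 minus WT under NR, against 0.51, 0.98 and 0.71 under INT-747.

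INT-747 and NR were compared in WT mice to show how the treatments differ without disease. Idi1 (chromosome 13, 8885501 to 8892451), which makes the isoprenoid building block of cholesterol, was at 70.2 ± 11.2 CPM under INT-747 and 26.6 ± 3.52 under NR (log2 1.40, SE 0.20, adjusted p = 0.0909). Akr1c18 (chromosome 13, 4132615 to 4150654), which inactivates progesterone, was called, at 58.9 ± 3.79 against 26.1 ± 3.81 CPM (SE of log2 0.12, adjusted p = 0.00293). The pseudogene Rpl3-ps1 on chromosome X was the other called gene, at 90.6 ± 5.61 against 181.2 ± 13.5 CPM (SE of log2 0.09, adjusted p = 0.00293). Reads it may share with Rpl3, which were not examined, make its value uncertain.

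Both called genes separated the 6 WT mice without overlap, as did 12.9% of all genes, where chance gives 10%. An unadjusted p under 0.05 was found for 787 genes, against 785 by chance. The next genes by p, not past the threshold, were Fmod (log2 1.85), Josd1 (−0.55), the branched-chain aminotransferase Bcat1 (4.02), Chrdl1 (2.81), Ucp2 (−1.39) and the long noncoding Gm47939 (2.03) and Gm46349 (4.44), at an adjusted p = 0.0909 to 0.156. The count was 4 without WT replicate 3 under INT-747 and 5 without Tg26 replicate 3 under NR, 5 with the sex term, where Idi1 was past the threshold, 6 with the clock score and 2 with a replicate block. DESeq2 called 61 genes and limma-voom 2.

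Of the lists, 6 were called in WT mice. Fatty acid oxidation genes were lower under INT-747 in 26 of 28 members (median −0.33, camera adjusted p = 1.5e-09), 3 adjusted over the list alone, with Decr1 at −0.58, Eci1 at −0.76 and Acadl at −0.42. Cholesterol genes were higher in 19 of 22 (0.22, adjusted p = 4.1e-07), 5 adjusted over the list alone, with Mvk at 0.91 and Msmo1 at 0.44. Loop of Henle genes were higher in 10 of 10 (0.44, adjusted p = 4.4e-07), 4 adjusted over the list alone, with the cotransporter Slc12a1 at 0.92, Ptger3 at 0.88 and Umod at 0.68. Lipogenesis genes (14 of 18, 0.19, adjusted p = 0.00549, with Scd1 at 2.60 and Fads1 at 0.44), interferon-stimulated genes (18 of 24, 0.33, adjusted p = 0.0227, with Rtp4 at 0.83) and fibrosis genes (19 of 25, 0.28, adjusted p = 0.0312, with Acta2 at 0.81) were higher too. The adjusted p of the 6 lists was 0.573 to 0.907 with an estimated correlation. FXR targets (8 of 13 higher, 0.19, adjusted p = 0.235) and NAD metabolism genes (15 IDs higher and 15 lower, 0.01, mean −0.18, adjusted p = 0.74) were not called. Apoc3 stood at 2.31 (SE 0.81), Fgfr4 at 0.28, Nr0b2 at 0.82 (SE 0.63) and Ido2 at 0.68.

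The same comparison in Tg26 mice asks how the treatments differ in the diseased kidney. Idi1 was at 82.5 ± 10.3 CPM under INT-747 and 29.1 ± 8.55 under NR (SE of log2 0.20, adjusted p = 0.0158), Hmgcs1 at 824.3 ± 70.3 and 401.7 ± 89.8 (1.04, SE 0.17, adjusted p = 0.0228) and Dhcr7 1.22 higher on the log2 scale (SE 0.26, adjusted p = 0.0353). Of 18 NRF2 and oxidative stress genes, which were not called as a list (10 higher, 8 lower, median 0.05, adjusted p = 0.142), Gclc (log2 0.83), Gclm (0.71) and Gsr (0.77) were called higher. The profibrotic Ccn2 fell from 141.3 ± 25.4 to 73.8 ± 24.6 CPM (−0.94, SE 0.22, adjusted p = 0.0427) and Col8a1 by a log2 of −1.07. Kynu, an enzyme on the path from tryptophan to NAD, fell from 20.3 ± 18.7 to 3.35 ± 0.716 CPM (−2.60, SE 0.60, adjusted p = 0.0436), but the female Tg26 mouse under NR had 41.9 CPM, and with the sex term Kynu was not past the threshold (log2 −1.51, SE 0.34, adjusted p = 0.0652).

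Here 688 genes were called, 456 higher and 232 lower under INT-747, and 135 changed at least 2-fold. All 688 separated the 6 Tg26 mice without overlap, as did 28.0% of all genes. The largest increases were in Kif20b (log2 2.55), Bcat1 (2.27), the transcriptional repressor Bcl6 (2.10), Tsga10 (1.73), Rnf24 (1.64), the sodium and proton exchanger Slc9a8 (1.61), the amino acid transporter Slc6a15 (1.59), Myo5a (1.56), Idi1, Gas2 (1.48), Apold1 (1.38) and the acetyl-CoA transporter Slc33a1 (1.35). Besides Kynu, the largest decreases were in Bbox1 (−2.56), the last enzyme of carnitine synthesis, Lrat (−2.13), which esterifies retinol, Nr1i3 (−1.96), Them6 (−1.65), Armc12 (−1.55), Hpdl (−1.44), the serine synthesis gene Psat1 (−1.43), Fyb2 (−1.41), Acnat1 (−1.40), Abhd15 (−1.39) and Zfp467 (−1.38).

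Among 13 FXR targets 3 rose and 1 fell in Tg26 mice under INT-747 relative to NR: Fgfr4 (log2 0.58, SE 0.11), Nr1h4 (0.76, SE 0.16) and Slc51a (from 82.0 ± 26.2 to 163.8 ± 11.4 CPM) rose, and Cyp27a1, which starts the acidic pathway of bile acid synthesis, fell (−0.55, SE 0.11). The list was not called (5 higher, 8 lower, median −0.12, camera direction higher, adjusted p = 0.806), and Nr0b2 stood at −0.12 (SE 0.62) with under 1 CPM in each group. Of NAD metabolism genes, Pnp (0.47), Acmsd (1.11), which diverts tryptophan carbon from NAD synthesis, and Nadsyn1 (0.46) rose and Kynu fell, while Nmrk1 stood at 0.85 (adjusted p = 0.0733). That list was not called (18 IDs higher, 12 lower, median 0.10, mean −0.09, adjusted p = 0.0707).

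Camera called 11 lists in Tg26 mice, 4 higher and 7 lower under INT-747. Cholesterol synthesis genes were higher in 19 of 22 members (median 0.28, adjusted p = 1.5e-05), 6 adjusted over the list alone. Those of the unfolded protein response were higher in 13 of 20 (0.21, adjusted p = 0.0104), with Hsp90b1 at 0.70, Pdia6 at 0.65 and Creld2 at 0.93 called. Proximal tubule genes were higher in 14 of 20 (0.34, adjusted p = 0.0414), with Keg1 called higher at 1.35 and Slc5a12 called lower at −0.79. The nuclear-encoded respiratory chain was higher in 32 of 38 (0.12, adjusted p = 0.0414), as in Ndufs1 at 0.27. Fibrosis genes (24 of 25 lower, −0.77, adjusted p = 0.000479, with Ccn2 and Col8a1 called) and intercalated cell genes (10 of 10, −0.50, adjusted p = 0.00192, with Foxi1 called at −1.30) were lower. So were tubular injury genes (16 of 16, −1.01, adjusted p = 0.00523, with Spp1 at −1.32 and Lcn2 at −2.95 not past the threshold) and cell cycle genes (23 of 23, −0.56, adjusted p = 0.00523, with Mcm4 called at −0.77). The other lower lists were fatty acid oxidation genes (25 of 28, −0.26, adjusted p = 0.00523, 5 adjusted over the list alone), podocyte genes (14 of 15, −0.33, adjusted p = 0.0106, with Wt1 at −0.83 and Nphs1 at −0.67) and principal cell genes of the collecting duct (9 of 10, −0.53, adjusted p = 0.0164, with Aqp2 called at −0.68). With an estimated correlation the adjusted p of the 11 lists was 0.779 to 0.843.

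The Tg26 treatment difference depended on the model. With the sex term 37 genes were called, 35 of them among the 688, and Idi1 (log2 1.31) and Gclc (0.98) were among them. Of the 24 genes named for the largest changes, Idi1, Them6 and Abhd15 were called with it and the other 21 were not, where the Tg26 mean under NR rests on 2 libraries. Kif20b then stood at log2 2.21 (SE 0.48, adjusted p = 0.0652), Bcl6 at 1.99 (SE 0.40, adjusted p = 0.0652) and Bbox1 at −1.78 (SE 0.37, adjusted p = 0.0598). The called FXR targets and NAD metabolism genes, Hmgcs1, Dhcr7, Gclm, Gsr, Ccn2, Col8a1, Hsp90b1, Pdia6, Creld2, Keg1, Slc5a12, Foxi1, Mcm4 and Aqp2 were not past the threshold with it either. A replicate block gave 71 genes, edgeR with only the 6 Tg26 libraries 0, DESeq2 2167 and limma-voom 750. The clock score gave 1235 genes, and with the sex term added it gave 576, 369 of them among the 688. In the 12-library fit the unadjusted p was under 0.05 for 4281 genes. Leaving out single libraries gave 73, 253 and 421 without WT replicates 1, 2 and 3 under INT-747, and 0 and 12 without Tg26 replicates 1 and 3 under INT-747. It gave 361 and 232 without WT replicates 2 and 3 under NR, and 47, 2320 and 63 without Tg26 replicates 1, 2 and 3 under NR. The called lists numbered 18 without Tg26 replicate 2 under INT-747 and 7 without Tg26 replicate 1 under NR.

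**Figure D3:**
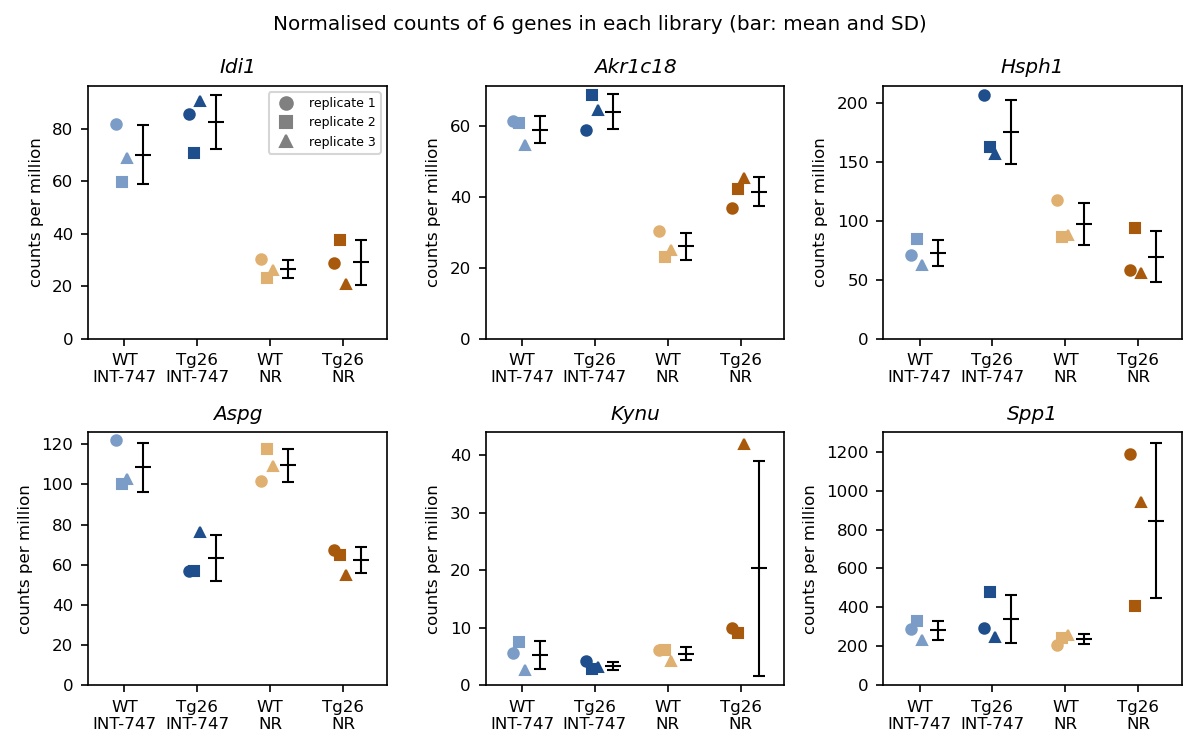
CPM of 6 genes in each library, on linear axes from 0, with points for replicates and a bar for mean and SD (n = 3). Idi1 was at 59.7 to 90.7 CPM in the 6 libraries under INT-747 and 20.7 to 37.8 under NR, and Aspg at 54.8 to 76.4 CPM in the 6 Tg26 libraries and 100.3 to 122.4 in the 6 WT libraries.

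The interaction tests whether the genotype effect differed between INT-747 and NR. No gene was past the threshold with edgeR, where 2428 had an unadjusted p under 0.05; DESeq2 called 247 and limma-voom 0. Genes of smallest p, at an adjusted p = 0.123 to 0.159, were Farsb (log2 1.22, SE 0.19), Chordc1 (1.05), Them4 (1.05), Mtus1 (0.93), Josd1 (0.75), Rpl3-ps1 (0.79), Hsph1 (1.76, SE 0.30), Cbx7 (−0.88), the plasminogen activator gene Plat (−0.95) and the pseudogene Gm10443 (−1.36). The count was 1 without WT replicate 3 under INT-747 and 174 without Tg26 replicate 2 under NR, and 0 with a replicate block.

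By list, 10 had a lower and 3 a higher genotype effect under INT-747 than under NR. Fibrosis genes had a lower effect in 25 of 25 members (camera adjusted p = 6.2e-06), 3 adjusted over the list alone, with Ccn2 at −1.34, Acta2 at −1.24 and Col8a1 at −1.26, and tubular injury genes in 15 of 16 (adjusted p = 0.00116), with Spp1 at −1.58. Lower effects were also found for macrophage genes (20 of 20, adjusted p = 0.0119, H2-Eb1 at −4.01 with SE 2.15), T cell genes (12 of 13, adjusted p = 0.0446, Cd5 at −2.63) and interferon-stimulated genes (18 of 24, adjusted p = 0.0446, Parp14 at −1.06). Loop of Henle genes (10 of 10, adjusted p = 0.00417, Slc12a1 at −1.07 and Umod at −0.80), intercalated cell genes (10 of 10, adjusted p = 0.0119, Foxi1 at −1.12) and cell cycle genes (22 of 23, adjusted p = 0.0119, Mcm4 at −0.78) had lower effects as well. So had podocyte genes (13 of 15, adjusted p = 0.0127, Tcf21 at −1.10) and endothelial genes (13 of 15, adjusted p = 0.0219, Sox17 at −0.87). Effects were higher for the unfolded protein response (15 of 20, adjusted p = 0.0124, Pdia4 at 0.77 and Creld2 at 1.02), the nuclear-encoded respiratory chain (33 of 38, adjusted p = 0.0186) and proximal tubule genes (15 of 20, adjusted p = 0.0308, Keg1 at 2.06). The adjusted p of the 13 lists was 0.651 to 0.664 with an estimated correlation, and 8 lists were called without Tg26 replicate 3 under INT-747.

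Across genes, which are not independent replicates, the genotype effects under INT-747 and NR correlated with a Pearson r of 0.318 and a Spearman rho of 0.105. The Pearson r was 0.016 without Tg26 replicate 2 under INT-747 and 0.205 without Tg26 replicate 1 under NR. The treatment differences in WT and Tg26 mice correlated with r = 0.145 and rho = 0.00516; r was 0.227 and 0.0523 without WT replicates 2 and 3 under INT-747, −0.0498 without WT replicate 2 under NR and 0.0586 without Tg26 replicate 2 under NR. Of the 42 genes called between genotypes under INT-747, 64.3% had the same sign and 35.7% the opposite sign under NR, a contrast that shares no library with it; in simulations with no difference between any of the groups 54.0% were opposite. In the Tg26 treatment difference, which shares the Tg26 mice under INT-747, 4.76% of the 42 were opposite, against 4.05% in these simulations. With the sex term, 8.24% of the 340 genes called under NR were opposite under INT-747, against 50.4% in the simulations, and 94.4% were opposite in the Tg26 treatment difference, against 94.6%. In the simulations each gene varied on its own. Genes that move together in single mice could depart from the simulated shares by chance, so these shares give no test.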

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

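Of the tests in this part, those of the sex of the mouse, of library depth, of the female library behind the immune, matrix and injury lists, of lymph node or fat, of tissue handling, and of the time of day where clock scores overlap or with the score as a covariate were chosen after the result was seen, and so was the adjustment over lists in the heat shock tests.

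The genotype effect differed between INT-747 and NR in 13 of 34 lists by camera on the interaction, which is why they are described here. The median log2 of the difference, INT-747 minus NR, was −1.13 for fibrosis and matrix, −1.25 for tubular injury, −0.78 for loop of Henle, −0.69 for cell cycle, −0.45 for intercalated cell, −1.06 for macrophage, −0.42 for podocyte, −0.23 for endothelial, −0.45 for interferon-stimulated and −0.80 for T cell genes. It was 0.21 for the unfolded protein response, 0.16 for the nuclear-encoded respiratory chain and 0.43 for proximal tubule genes. With an estimated correlation 0 lists were called. Splits of the 12 libraries exchanged treatment labels among the WT and among the Tg26 libraries, with genotype kept. Some of them kept the real treatment groups of a genotype. Of 100 drawn, the real one included, 56 called at least 13 lists and the highest other called 23, so chance cannot be excluded. For genes the real split called 0 with edgeR, where 2428 had an unadjusted p under 0.05. The highest of the other splits called 825. It kept the Tg26 mice in their real treatment groups and exchanged WT mice only, so it is not a split without real groups. Other drawn splits with the same Tg26 groups called 0, and what lies behind the 825 was not tested. All 100 splits called at least as many as the real one, which a real count of 0 makes certain.

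Tg26 replicate 3 under NR stood apart from the other Tg26 libraries under NR, with the Xist count of 5816 and the absence of 4 Y-linked genes that a female mouse predicts, and with a total count of 25116121, within the range of the others, which argues against library depth. On a score from the 571 genes called between the INT-747 groups alone, 0 being the WT and 1 the Tg26 mean, it had −0.142, within −0.174 to 0.442 of the WT mice under NR, as a WT sample under a Tg26 label predicts. WT replicate 1 under NR, at 0.442, lay within 0.369 to 0.475 of the other Tg26 mice under NR, as an exchange would need. Tg26 replicate 1 under NR, at 0.369, lay within the WT range too. This genotype score also came from groups whose clock scores did not overlap, so it cannot tell genotype from clock. The clock score was also low in Tg26 replicate 3 (0.576) and high in WT replicate 1 (3.25), and Aspg, chosen after its values were seen, followed the labels, at 54.8 CPM in Tg26 replicate 3 against at most 76.4 in the other Tg26 libraries and at 101.6 in WT replicate 1 against at least 100.3 in the other WT libraries. A wrong label stays open, and so does an effect of sex on the disease, which 1 female library leaves untested.

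The 7 lists of tubular injury, fibrosis and matrix, macrophage, T cell, cytokine, complement and interferon-stimulated genes had lower medians in Tg26 mice under INT-747 than under NR, with 2 of 7 called lower in the 12-library fit and 7 of 7 without Tg26 replicate 2 under INT-747. With the sex term 6 of the 7 were called lower at the preset correlation and all 7 medians lay further below 0, which argues against the female library as their source, while with an estimated correlation and by fry 0 lists were called with or without that term. Without Tg26 replicate 1 under NR, the library with the highest Lcn2 (77.2 CPM), 0 of the 7 were called by camera and their medians lay between −0.27 and 0.19, as predicted if that library alone carried the pattern, though 2 of the 7 were still called lower in the interaction and 1 of the 2 libraries left in the group is female. Lymph node or perirenal fat cannot be excluded: the adipocyte list had a median log2 of −0.35 with the sex term and was not called. A treatment effect on the disease stays open as well, since severity may differ between 3 mice of a group whatever the treatment.

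Heat shock genes were higher in Tg26 mice under INT-747: all 8 first noticed, Hsph1, Hsp90aa1, Chordc1, Ahsa1, Cacybp, Hspe1, Stip1 and Hspa1b, had a median log2 of 0.68, and the cold-inducible Rbm3 and Cirbp one of −0.35. Of 12 other heat shock genes, listed before their values were seen, 11 were higher (median 0.43, camera adjusted p = 0.000131 over the 6 lists made for such tests), as a wider heat shock response predicts, but 0 of the 12 were called and with an estimated correlation the adjusted p was 0.113. The clock score was 2.55 higher in Tg26 than in WT mice under INT-747. With the score as a covariate the median of the 12 genes fell to 0.10 (camera adjusted p = 0.4455 at an estimated correlation). That of the 8 fell to 0.47 (adjusted p = 0.0115 at an estimated correlation), but they were chosen from these libraries, so this p is no independent test. The scores of the genotypes did not overlap under INT-747 and varied within groups mainly under NR (SD 1.56 in Tg26 and 2.04 in WT mice). A covariate therefore cannot separate clock from genotype under INT-747, and the falls do not decide between them. Another time of day at collection is a candidate explanation for that contrast. Between Tg26 mice under INT-747 and the remaining 2 under NR with the sex term, where scores overlapped and neither clock list was called (adjusted p = 0.468), the 8 genes, chosen from the same INT-747 libraries, had a median of 0.69 and an adjusted p of 0.0445 at an estimated correlation, and the 12 genes 0.38 and 0.323. With the score as a covariate 7 of the 8 and 6 of the 12 were called in Tg26 mice between treatments, against 7 and 5 without it. The score thus did not take up these calls, but it could remove little, as the mean scores differed by 0.408 (SE 0.93). That fit had no term for the female library, and with the sex term 3 of the 8 and 0 of the 12 were called. For the 12 genes with the score the camera adjusted p was 0.16 at an estimated correlation. These counts therefore cannot decide on the clock. Nr1d1, chosen after its values were seen, was called too with the score (log2 −0.70, adjusted p = 0.0234). It is itself a gene of the score, so its value with the score decides nothing. Of the 10 output and repressor genes 5 were higher and 5 lower in that fit (median 0.006, camera adjusted p = 0.697). Time of day stays open. So does stress of tissue handling, whose immediate early list lay between the bounds set for that test (camera adjusted p = 0.0561, with an unadjusted p under 0.05).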

How the results depend on the processing

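Chosen after the result was seen were the clock score as a covariate, with and without the sex term, DESeq2 with the sex term, and set tests other than camera at the preset correlation with either term; the other settings were chosen before the data were examined.

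Counts of called genes in the genotype effect under INT-747 (42), under NR (0), the treatment difference in WT (2) and Tg26 mice (688) and the interaction (0) stayed within 1.5 times with RLE size factors, the stricter filter, limma-voom, edgeR without robust estimation and without genes on Y and Xist. Without a filter the first 2 were 64 and 6, with other genes tested. A replicate block gave 11 under INT-747 and 71 in Tg26 mice. The sex term gave 189, 340, 5 and 37 in the first 4. The clock score gave 2 under INT-747, 0 under NR, 6 in WT and 1235 in Tg26 mice. Together with the sex term it gave 1 under INT-747, 0 under NR, 10 in WT and 576 in Tg26 mice. Fits of only the groups compared gave 571 under INT-747 and 0 in Tg26 mice, with a dispersion from fewer libraries. DESeq2 gave 525, 967, 61, 2167 and 247, and with the sex term 876, 1310, 115, 1183 and 148. Apart from the fewer or other genes and libraries named, the cause was not tested.

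Leaving out 1 library gave 0 to 195 genes under INT-747, 0 to 785 under NR, 2 to 5 in WT mice, 0 to 2320 in Tg26 mice and 0 to 174 in the interaction; a group then held 2 libraries. The highest values came without Tg26 replicate 3 under NR (195 and 5) or Tg26 replicate 2 under NR (785, 2320 and 174), and the 0 in Tg26 mice came without Tg26 replicate 1 under INT-747. Called lists ranged from 5 to 15, 17 to 21, 4 to 8, 7 to 18 and 8 to 19 in the same order. The correlation across genes of the genotype effects ranged from 0.016 to 0.406 and that of the treatment differences from −0.0498 to 0.227. The share of genes called under INT-747 with the opposite sign in the Tg26 treatment difference, 4.76%, ranged from 0% to 25%. The 0% rests on 3 called genes, without WT replicate 1 under INT-747, and the 25% on 4, without WT replicate 2. The share was 94.4% for genes called under NR with the sex term, where the selection was on the other genotype effect.

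For lists, no filter gave 17 under INT-747 and 21 in the interaction, and the sex term 16 under INT-747. Camera with an estimated correlation called 0 lists in all 5 contrasts, also with the sex term or the clock score. Fry called 0 in all 5 without these terms and with the clock score; with the sex term it called 15 lists under NR, 1 in WT mice and 0 under INT-747, in Tg26 mice and in the interaction. With the clock score the median of the intercalated cell list under INT-747 turned from −0.24 to 0.063 in camera at either correlation and in fry, and the cause was not tested.

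Of 535 values of a gene in a contrast, those of all members of 4 lists included, 74 were past the threshold. Over the settings chosen beforehand, other than leaving out a library, 4853 values stayed on their side of the threshold, 172 fell short of it and 182 newly passed it. Leaving out 1 library gave 5852, 458 and 110. In each setting only the 74 values past the threshold could fall short. The 172 and 458 are therefore to be set against those 74 per setting, not against all values that stayed. Replicate numbers gave 5 of 18 same-numbered correlations over 0.1, and 4 samples correlated best with their own number, so no pairing of mice was read from them. Depths of 22286343 to 28952177 counts limit genes with few reads, such as Nr0b2.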

Other observations

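The split of 6 libraries into groups of 3 was tested for each contrast as planned, and tests in this part were written before their result was seen.

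A contrast of 3 against 3 has 10 splits, too few for a share under 0.05. In the genotype effect under INT-747 the real split called 42 genes and the highest other 1, and 8 lists against 19. Under NR it called 0 genes with edgeR, where 3244 had an unadjusted p under 0.05 and DESeq2 called 967 and limma-voom 0. The highest other called 181, and lists were 20 against 22. The split with 181 genes exchanged WT replicate 1 and Tg26 replicate 3, the libraries whose genotype scores lay in the range of the other genotype. It also parted high from low clock scores (2.87 to 3.57 against −0.608 to 0.576), so it cannot tell a wrong label from the clock. In WT mice genes were 2 against 1 and lists 6 against 8, and in Tg26 mice genes were 688 against 404 and lists 11 against 22. Splits at least as large as the real one numbered 1, 10, 1 and 1 for genes and 10, 4, 3 and 7 for lists, in this order.

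Josd1, Apobec3, Cbx7 and Rpl3 lie together on chromosome 15 and differed together, with log2 values of 0.36, −1.78, −0.92 and −0.58 between genotypes under INT-747; of these Cbx7 and Rpl3 were called. Of 50 other tested genes within 1 Mb (78674251 to 81091868), 17 had an unadjusted p under 0.05 in that contrast, 34.0% against 15.3% of all genes, at percentile 99.2 of random runs of neighbouring genes. A linked region that differs in strain background is a candidate explanation. Between genotypes under NR 2 of the 4 genes were higher and 2 lower (median 0.02, 0 called). The other genes of the region were not tested in that contrast. Between treatments in WT mice all 4 genes had an unadjusted p under 0.05, with 0 called. In WT mice between treatments the percentile was 75.2, and in the interaction 91.9, and the strain of the mice is not given in the sources used here.

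Aspg and Dio3os on chromosome 12 were lower in Tg26 mice under both treatments, past the threshold under INT-747 in the fit without the sex term and under both treatments with it. Of 74 other tested genes within 2 Mb (108275385 to 114127559), 15 had an unadjusted p under 0.05 in the mean of the genotype effects, 20.3%, at percentile 46.7 of random runs. This share equals the median of the runs, 20.3%, and argues against a linked region of different strain background in which many genes differ. A region that changes only a few genes would not raise the share and stays open. Where the transgene lies was not examined.

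Further members of 4 lists had the following values for INT-747 minus NR in Tg26 mice, none of them past the threshold. Tubular injury genes had log2 values of −1.58 for Sox9, −1.81 for Timp1, −1.09 for Cd44, −1.56 for Krt19, −0.89 for Clu, −0.93 for Krt18, −1.24 for Cdkn1a, −0.67 for Vim, −0.07 for Itgb6, −0.69 for Vcam1, −0.75 for Anxa3, −0.35 for Cryab, −2.67 for Krt20 and −0.94 for Havcr1. Podocyte genes had −0.23 for Clic5, −0.22 for Plce1, −0.33 for Podxl, −0.16 for Ptpro, −0.26 for Thsd7a, −0.33 for Cdkn1c, −0.39 for Magi2, −0.59 for Kirrel, −0.13 for Synpo, −0.73 for Tcf21 and −0.09 for Dach1. FXR targets had −1.08 for Pltp, −2.22 for Abcc3, −0.89 for Fetub, 0.26 for Slc10a2, −0.07 for Abcc2, −2.21 for Apoc3, −0.32 for Slc51b and 1.63 for Ugt2b38.

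NAD metabolism genes in the same contrast, none of them past the threshold, had log2 values of 0.23 for Haao, 0.10 for Sirt2, 0.58 for Afmid, −0.15 for Sirt1, 0.15 for Nampt, 0.10 for Nadk2, −0.04 for Naprt, 0.07 for Sirt3, 0.11 for Parp1, −1.75 for Tdo2, 0.32 for Nmnat1, 0.46 for Nadk, −1.67 for Bst1, −0.16 for Cd38, 0.23 for Qprt, 0.49 for Ido2, 0.33 for Nt5e, 0.26 for Nmnat3, −0.25 for Sirt6, −0.24 for Parp2, −0.16 for Kmo, 0.11 for Sirt5 and −0.70 for Aox1. Nnt has 2 IDs with different values, so none is given for it.

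Lists called in none of the 5 contrasts, besides FXR targets and NAD metabolism, had these medians for Tg26 minus WT under INT-747 and under NR. They were −0.38 and 0.02 for the distal convoluted tubule, −0.08 and 0.13 for the renin-angiotensin system, 0.03 and −0.04 for cystic and ciliary genes, −0.76 and −0.68 for blood, and 0.10 and 0.02 for p53 targets. For INT-747 minus NR in WT and in Tg26 mice they were 0.12 and −0.28, 0.09 and −0.16, 0.08 and 0.12, 0.13 and −0.11, and 0.05 and 0.21 in the same order. The adrenal and skeletal muscle lists had 2 tested members each and were not tested.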
